A study of Mus musculus with 18 samples.

How the data were processed

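Each library was the RNA bound to tagged ribosomes, taken from the cerebella of 4 mice (2 males and 2 females according to the labels), and was hybridised to 1 short-oligonucleotide expression array. The tag, a green fluorescent protein joined to the ribosomal protein L10a, is expressed under the Pcp2 (L7) promoter, which is active in Purkinje cells. The 6 groups crossed 2 genotypes (wild type, and mice carrying the CGG90Fmr1 transgene under the same promoter) with 3 ages (4, 8 and 12 weeks), with 3 libraries in each group. Genotypes are those of the labels throughout.

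The deposited values are on the log2 scale, 1 value per probe set and library, made by the authors with GCRMA according to their processing notes. GCRMA corrects background by probe sequence, normalises between arrays and summarises each probe set. Which arrays were normalised together is not stated, and background correction was not varied. The array number limits the precision. Median log2 values per library were between 2.56 and 2.72, 75th percentiles between 6.30 and 6.78, and maxima between 15.7 and 15.9. Between 36.6% and 39.2% of the probe sets of a library had a log2 value of at least 4.

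Of 45101 probe sets, 34958 had exactly 1 gene symbol in the annotation, 932 had several, 9211 were not listed there and 64 of the file's probe sets were array controls. Symbols were checked by gene identifier against a reference gene table, which changed 0 symbols. For each gene the probe set with the highest mean over all libraries was used, and genes were tested if it reached a log2 value of at least 4 in at least 3 of the 18 libraries, which left 10068 genes. A gene whose probe sets carry no symbol in the annotation was not tested.

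Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 6 group means, residual degrees of freedom 12, two-sided, prior degrees of freedom 2.55). P-values were adjusted by the Benjamini-Hochberg method over the 10068 genes, with a threshold of 0.05. The comparisons were the genotypes at each age and averaged over the ages, the dependence of the genotype difference on age (a moderated F test), the ages in pairs averaged over both genotypes, and 12 against 4 weeks within each genotype. Comparisons of single values used exact permutation tests, two-sided, in which genotype labels were exchanged within age. For list means at 12 against 4 weeks, age labels were exchanged within genotype instead. Permutation p-values of correlations came from 100000 random exchanges of libraries within groups. That of the variance share between groups came from as many random exchanges over all libraries.

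In every comparison but the F test, 30 gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. The lists covered 10 sets of cell type markers (Purkinje cells, granule cells, astrocytes and Bergmann glia, oligodendrocytes and their precursors, microglia, endothelial and mural cells, cerebellar interneurons, blood cells, choroid plexus) and 20 gene groups (immediate early genes, CGG repeat RNA-binding proteins, FMRP and its partners, group I metabotropic glutamate receptor signalling, calcium handling and ion channels, hereditary ataxia genes, heat shock proteins, the unfolded protein response, proteasome subunits, oxidative phosphorylation, cytoplasmic ribosomal proteins, microRNA biogenesis, p53 response, perineuronal net and matrix, neuronal immaturity genes, cholesterol biosynthesis, interferon response, antigen presentation, clock genes, sex-linked genes).

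The comparisons, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. For each comparison the rule named Fmr1, Tardbp, Pcp2 and Rpl10a, up to 8 genes in each direction past the threshold, the 3 genes of smallest p in each direction where fewer than 5 passed, and up to 4 members of each list that passed, chosen by smallest p in the list's direction. Members of the lists of CGG repeat RNA-binding proteins, FMRP and its partners and Purkinje markers that passed singly were to be named as well.

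Replicate numbers were checked as a pairing. At 4 weeks the same number in both genotypes had the same immunoprecipitation date, and residuals of same-number pairs correlated at r between 0.0205 and 0.609. At 8 weeks only the replicate 3 pair shared a date, residuals of same-number pairs correlated at r between -0.351 and -0.0369, and at 12 weeks at r between -0.207 and -0.0404, so numbers were not used as pairs in the tests reported. Part of the library titles carries numbers that change with age in 1 case and with both age and genotype in the other. These numbers were not used as a term because age coincides with the former, and genotype at 8 and 12 weeks with the latter.

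The fits were tested on simulated data in which residuals of these libraries were reused and 200 genes were shifted, 10 times per setting. In the genotype comparison at 4 weeks 1.65% of genes shifted by log2 1 and 45.6% of genes shifted by log2 2 were called. Averaged over ages these shares were 38.1% and 84.7%, and at 12 against 4 weeks they were 20.2% and 74%. With no gene shifted, the mean number of calls was 1.3, 0.4 and 0 in the same comparisons. A proteasome list shifted by log2 -0.5 was called by camera with the preset correlation in 10 of 10 simulations in each of the 3 comparisons. With no shift it was still called in 2, 3 and 1 of 10, and on average 4, 4.1 and 2.1 other lists were called, so camera at the preset correlation called too many lists in simulated data of this kind. With an estimated correlation the unshifted list was called in 0 of 10 and the shifted list in 1, 7 and 4 of 10.

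Alternatives were a stricter filter and none, all probe sets past the filter or the median of a gene's probe sets, quantile normalization, cyclic loess, centring of each array on its median, eBayes with trend and robust estimation, array weights, other thresholds, only the arrays compared, replicate number or immunoprecipitation date as a block, and leaving out each library in turn. A pair of alternatives was added after the data were seen: leaving out the libraries labelled CGG90 12 weeks replicates 1 and 2, and a covariate for markers of other cell types. So were the fit of the 4-week libraries alone with a replicate block, the list tests in the 4-week libraries alone, the other Fmr1 probe sets, the alternatives for the correlation of genotype differences between ages, the repeats of each alternative for single lists, and the correlation of the cholesterol list with the other-cell markers.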

Results

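RNA on the ribosomes of mouse Purkinje cells, the output neurons of the cerebellar cortex, was measured on expression arrays in 18 libraries. Wild-type mice and mice carrying the CGG90Fmr1 transgene were compared at 4, 8 and 12 weeks of age, with 3 libraries per group and 4 mice pooled per library. The transgene places an Fmr1 construct with 90 CGG repeats, a repeat number in the range carried in fragile X-associated tremor/ataxia syndrome, under a Purkinje cell promoter. No group carried an Fmr1 transgene with a short repeat. A difference between genotypes therefore cannot be assigned to the repeat rather than to the added Fmr1 transcript or the transgene itself. Pearson's r across the 10068 tested genes, which are not independent replicates, was between 0.891 and 0.957 for the 18 pairs of libraries of the same group. The median SD of a gene between replicates was log2 0.40 in both groups at 4 weeks and between 0.47 and 0.52 in the 4 groups at 8 and 12 weeks.

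Fmr1, the gene whose transcript the transgene adds, stood far above wild type in all CGG90 libraries at 4 and 8 weeks, but in only 1 of the 3 libraries labelled CGG90 at 12 weeks. With the brightest of its 3 probe sets (gene ID 14265), the mean log2 value was 11.63 ± 0.10 (SD, n = 3) against 6.98 ± 0.57 in wild type at 4 weeks, and 11.52 ± 0.46 against 7.35 ± 1.54 at 8 weeks. These differences of log2 4.65 and 4.18 correspond to 25.1-fold and 18.1-fold higher values. At 12 weeks the library labelled CGG90 replicate 3 had 12.01, whereas the libraries labelled CGG90 replicates 1 and 2 had 7.10 and 6.03, below the lowest wild-type library of that age at 7.63. Within immunoprecipitation dates shared by both genotypes, the Fmr1 difference was log2 5.33, 4.18 and 4.43 at 4 weeks and 3.99 at 8 weeks, and -1.07 on the 1 shared date at 12 weeks, which held the libraries labelled CGG90 replicates 1 and 2. Over all ages Fmr1 rose by log2 3.09 on average (exact permutation p = 0.003 over 8000 within-age arrangements, 0.018 adjusted over 12 tests of Fmr1 probe sets), and 7 of 9 libraries labelled CGG90 lay above the highest wild-type library of all ages. A second probe set gave differences of log2 3.84, 3.51 and 1.39 at the 3 ages (exact permutation p = 0.001 over all ages, 0.012 adjusted). With it the libraries labelled CGG90 12 weeks replicates 1 and 2 had 6.82 and 5.06, where the highest wild-type library had 6.42 and the other CGG90 libraries 8.38 or more, so 8 of 9 lay above wild type. The remaining, dimmest probe set gave -0.01, -0.79 and 0.59 (exact permutation p = 0.806), so it did not follow the transgene. At a single age the smallest p that 3 against 3 libraries allow is 0.1, and the exact permutation p was 0.1 at 4 and 8 weeks and 1 at 12 weeks with the brightest probe set.

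**Figure D1:**
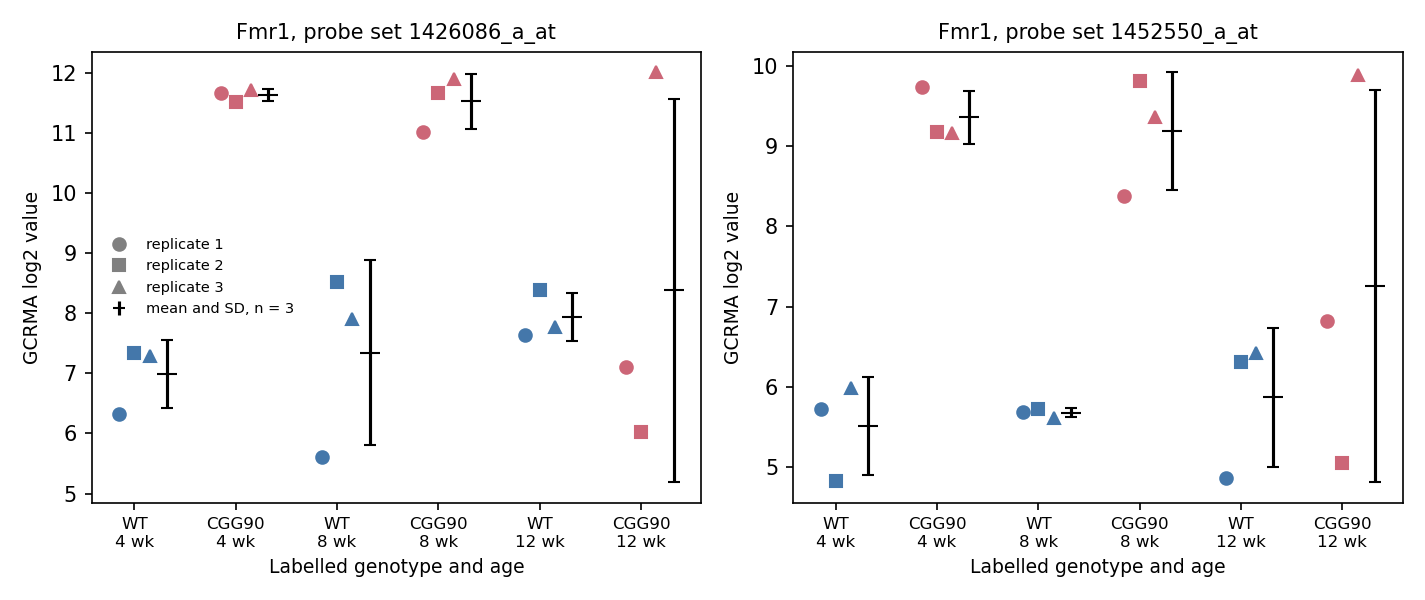
Fmr1 log2 value (GCRMA) of each library by labelled genotype and age, for the brightest (left) and a second probe set (right), with group means and SD (n = 3). In the left panel all CGG90 libraries at 4 and 8 weeks lie at 11.01 or above, and the libraries labelled CGG90 12 weeks replicates 1 and 2 lie at 7.10 and 6.03, among the wild-type values.

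Purkinje cell transcripts were abundant in every library, and transcripts of other cerebellar cells varied widely between replicates of the same group. The mean log2 value of 18 Purkinje markers was between 11.76 and 12.48 per library. Pcp2, the gene whose promoter drives the tag, reached 14.55 to 15.01, close to the array maximum, and Rpl10a, the ribosomal protein used as tag, 12.32 to 13.20. The mean of 66 markers of granule cells, astrocytes and Bergmann glia, oligodendrocytes, microglia, endothelial cells and interneurons ran from 6.30 to 9.32. Its range within a group reached log2 2.49, while group means lay between 7.65 and 8.28. Among single markers, Mbp, a myelin component, ran from 10.60 to 14.05, Cbln1, a granule cell synapse organiser, from 9.82 to 12.64, and Laptm5, a microglial lysosomal gene, from 5.51 to 10.60, whereas Hopx, of the astrocyte list, ran from 11.94 to 12.59 and Slc32a1, of the interneuron list, from 10.85 to 12.15. Whether Purkinje cells add to the signal of these markers, those of the interneuron list above all, was not tested. None of the marker lists passed camera in a comparison of genotypes. Pcp2 differed by log2 0.07, 0.08 and 0.04 between genotypes at 4, 8 and 12 weeks, and Rpl10a by -0.13, 0.01 and -0.08. Their signs were not stable: at 4 weeks Pcp2 was at -0.01 without wild-type replicate 3 and Rpl10a at 0.03 without wild-type replicate 2, and at 8 weeks Rpl10a was at -0.01 after quantile normalization.

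**Figure D2:**
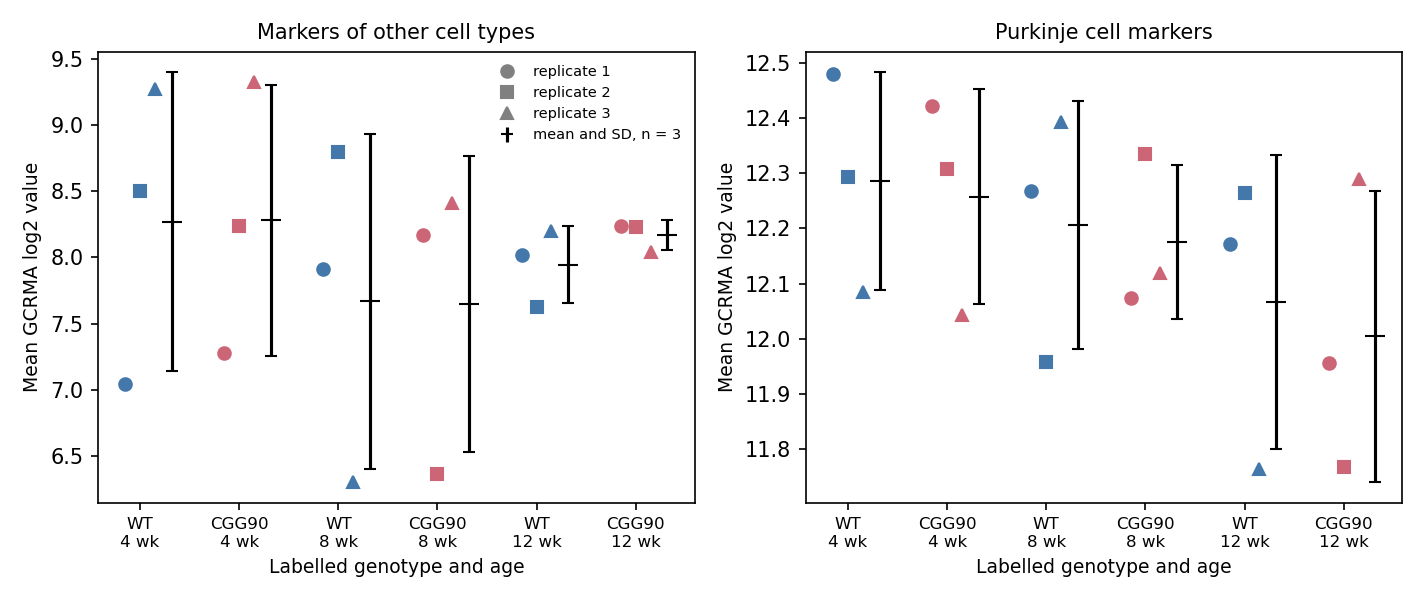
Mean log2 value (GCRMA) of 66 markers of other cell types (left) and of 18 Purkinje cell markers (right) in each library, by labelled genotype and age, with group means and SD (n = 3). The other-cell mean ranges from 6.30 to 9.32 over the libraries and the Purkinje mean from 11.76 to 12.48.

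At 4 weeks, the genotypes were compared in young Purkinje cells. Bace2, a membrane protease, had the smallest p of all genes and lay above wild type in 3 of 3 libraries, with a log2 value of 5.25 ± 0.49 (SD, n = 3) against 2.95 ± 0.11, a difference of 2.31 ± 0.43 (SE) that did not pass adjustment (adjusted p = 0.941). Its other 4 probe sets had means below 2.5 in all groups and differences of 0.08 or less at 4 weeks. Fmr1 was higher in 3 of 3 libraries by 4.65 ± 1.11 (SE). Gm38396 had a difference of 1.20. On the lower side were Kdm4b, a histone demethylase, at -0.88, Hinfp, a transcription factor of histone genes, at -1.22, and Anapc1, a subunit of the anaphase-promoting complex, at -1.26, all with adjusted p of 1.00. Tardbp, which encodes the RNA-binding protein TDP-43, had a difference of -0.19, whose sign changed to 0.01 without CGG90 replicate 1, 0.03 without wild-type replicate 3 and 0.05 with array weights. Of the 23 tested CGG repeat RNA-binding proteins, 17 were lower (median -0.07, adjusted p = 0.581), and of 9 genes of FMRP and its partners 7 were lower (median -0.04, adjusted p = 0.817) although the list's mean was positive at 0.41 through Fmr1 itself. Adjusted over the list alone, 1 gene passed, Fmr1 itself (adjusted p = 0.00782), which restates the transgene. The smallest adjusted p of a list belonged to the p53 response, with 11 of 13 genes lower and a median of -0.29 (adjusted p = 0.107, and 0.284 with an estimated correlation). Its mean was lower by 0.27, 0.22 and 0.32 within the 3 immunoprecipitation dates.

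In limma 0 of 10068 genes passed at 4 weeks and 49 had an unadjusted p below 0.05, where chance would give 503.4, and 0 lists passed with camera at either correlation or with fry. This fit pools the spread of all groups and leaves variation shared by immunoprecipitation date in the error: the share of genes below 0.05 was 0.487%, with the 4-week libraries alone 1.27%, and with the replicate number, which is the date at that age, as a block added to these 2.98%. The p53 list had an adjusted p of 0.0418 with the 4-week libraries alone and 0.0736 with the block added. The Fmr1 difference passed when the 4-week libraries were fitted alone (adjusted p = 0.0494), but not with the replicate block (adjusted p = 0.270). It also passed when the libraries labelled CGG90 12 weeks replicates 1 and 2 were left out (adjusted p = 0.0388), or replicate 3 of that group, since their spread enters the error of every comparison. Bace2 passed with array weights, at log2 2.42, and without wild-type 8 weeks replicate 2. Within the 3 immunoprecipitation dates the Bace2 difference was 1.78, 2.67 and 2.47. Without CGG90 replicates 1 or 3, camera called 5 and 3 lists, and without wild-type replicates 1, 2 or 3 it called 4, 1 and 2.

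At 8 weeks 1 gene passed. Cyb5rl (gene ID 230582), which encodes a cytochrome b5 reductase-like protein, rose by log2 3.02 ± 0.27 (SE) in CGG90, a lower bound since wild type was near the floor of the array, from 2.73 ± 0.10 (SD, n = 3) to 5.74 ± 0.71 (adjusted p = 0.00018). It was higher in 3 of 3 libraries. In the other 5 groups, CGG90 at 4 and 12 weeks included, its group means were between 2.69 and 2.75. It reached log2 4 only in the CGG90 libraries at 8 weeks, so it passed the filter through the group where it was high. Its SE pools the SD of 0.71 in that group with SDs of 0.01 to 0.10 in the groups near the floor. This SE was below the median of 0.47 for all genes, so the adjusted p rests on the small spread of floor values. Next in p, without passing, were Fasn, the fatty acid synthase, at 1.66 ± 0.34 (adjusted p = 0.335), Th, tyrosine hydroxylase, at 1.87 ± 0.40 (adjusted p = 0.493), and on the lower side Zfp287, a zinc finger gene, at -1.55 ± 0.27 (adjusted p = 0.237), 2700097O09Rik at -2.10 and Hid1, a gene of dense-core vesicle formation, at -2.06 (adjusted p = 0.292 each). Fmr1 was at 4.18 and Tardbp at -0.66 (adjusted p = 1.00 each). FMRP and its partners had a median of -0.12 and a mean of 0.18, and adjusted over the list alone Fmr1 itself passed (adjusted p = 0.0182). Genes of microRNA biogenesis were lower in 11 of 12 cases (median -0.47, adjusted p = 0.231, and 0.962 with an estimated correlation), and of the CGG repeat RNA-binding proteins 16 of 23 were lower (median -0.13, adjusted p = 0.575).

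Unadjusted p was below 0.05 for 374 of 10068 genes at 8 weeks, and 0 lists passed with camera or fry. On the 1 date shared by both genotypes the Cyb5rl difference was 2.25, and with date as a fixed block its adjusted p was 0.167. Genotype at 8 weeks coincides with a title number, also on this date, so genotype and that number cannot be told apart. The call also ended with a replicate block (adjusted p = 0.0700), when the 8-week libraries were fitted alone (adjusted p = 1.00), and with the stricter filter, which removes the gene. Counts were 2 without CGG90 replicates 2 or 3 or wild-type replicate 3, and also without the library labelled CGG90 12 weeks replicate 3, where Fmr1 was called, and camera called 3 lists without wild-type replicate 2 and 1 without CGG90 replicates 2 or 3 or wild-type replicate 3.

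At 12 weeks the comparison of labelled genotypes held the libraries labelled CGG90 replicates 1 and 2, whose Fmr1 was at the wild-type level. Ddn, which encodes dendrin, a postsynaptic protein, was at 7.28 ± 0.75 (SD, n = 3) in wild type and 3.57 ± 1.03 in the libraries labelled CGG90, lower in 3 of 3 by -3.71 ± 0.69 (SE). Its values in the other 4 groups had means between 3.02 and 4.24, so the wild-type libraries at 12 weeks stood apart. By the title number that changes with age and genotype, these wild-type libraries form a run that holds no other group. Genotype and run therefore cannot be told apart at this age, also within the shared immunoprecipitation date. Gpr146, a G protein-coupled receptor gene, was higher by 1.91 ± 0.35 in 3 of 3 libraries, from a wild-type mean of 3.18 near the floor (adjusted p = 0.465 for both genes). Further genes of small p were C630043F03Rik at 1.64, Snhg5, a host gene of small nucleolar RNAs, at 1.45, Miga2, a gene of mitochondrial fusion, at -1.44, and Nectin4, a cell adhesion gene, at -1.99 (adjusted p = 0.758 each). Fmr1 was at 0.45 and Tardbp at 0.37. Of the CGG repeat RNA-binding proteins 18 of 23 were higher (median 0.27, adjusted p = 0.431), and of FMRP and its partners 6 of 9 (median 0.45, adjusted p = 0.644).

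By limma 0 genes passed at 12 weeks with 534 below an unadjusted p of 0.05, and 0 lists passed with camera at either correlation or with fry. On the shared date, with 1 wild-type library and the libraries labelled CGG90 replicates 1 and 2, Ddn differed by -4.92 and Gpr146 by 1.86. Calls were 2 genes without wild-type replicate 2, 1 gene without wild-type replicate 3 and 1 without the library labelled CGG90 replicate 3, and 1 list without wild-type replicate 3. Without that CGG90 library Fmr1 was at -1.37. With the libraries labelled CGG90 12 weeks replicates 1 and 2 left out, 0 genes and 2 lists passed, in a test of 1 CGG90 library that is assumed to vary like the libraries of the other groups.

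Averaged over the ages, the comparison asked for a difference shared by all. Fmr1 was at 3.09 ± 0.64 (SE, limma adjusted p = 0.843). Zfp28 (gene ID 22690), a zinc finger gene, was the single gene of 10068 whose libraries separated the genotypes at each of the 3 ages. Chance would give 2.52 if 10% of genes did so at each age, but the shares seen were 4.35%, 7.22% and 8.62%. The mean Zfp28 difference was 1.87 ± 0.37 (adjusted p = 0.842), with the brightest of its 4 probe sets, and the others, near the floor, were at 0.17, 0.01 and -0.04. Group means of Zfp28 were 4.86, 4.34 and 5.28 in the libraries labelled CGG90 at 4, 8 and 12 weeks against 3.23, 2.81 and 2.84, and the libraries labelled CGG90 12 weeks replicates 1 and 2 had 5.13 and 7.01. Within dates Zfp28 was higher by 2.18, 1.66 and 1.02 at 4 weeks, 1.38 at 8 weeks and 3.23 at 12 weeks. Cyb5rl had the smallest p, at 1.02 ± 0.16 (adjusted p = 0.116), through its 8-week libraries. Lower in CGG90 were Hid1 at -0.86, Mydgf, a secreted growth factor, at -0.79 and Nectin4 at -0.96, with adjusted p of 1.00, and Tardbp at -0.16. Another Tardbp probe set was lower at all 3 ages, by -0.49, -1.18 and -0.25, and by -0.64 on average (exact permutation p = 0.008, 0.16 adjusted over the tests of all Tardbp probe sets), while the remaining ones were at 0.26, 0.11 and -0.04 on average. Adjusted over the list alone, Fmr1 itself passed among 9 genes of FMRP and its partners (adjusted p = 0.00226), of which 5 were lower. Purkinje markers went both ways, 8 higher and 10 lower, with a median of -0.02.

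Averaged over ages, 0 genes passed in limma, 211 had an unadjusted p below 0.05, and 0 lists passed with camera at either correlation or with fry. Fmr1 passed at 4.30 (adjusted p = 0.00106) with the libraries labelled CGG90 12 weeks replicates 1 and 2 left out. It also passed, with Zfp28 at 2.13, without the library labelled CGG90 12 weeks replicate 3 (Fmr1 2.49, adjusted p = 0.0449). Cyb5rl alone passed without CGG90 8 weeks replicate 2 or 3, with array weights or with the marker covariate, and 2 lists passed without wild-type 4 weeks replicate 3.

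The genotype differences at the 3 ages resembled each other little. Across the 10068 genes, which are not independent replicates, Pearson's r was 0.0871 between 4 and 8 weeks, -0.0411 between 4 and 12 weeks and -0.0505 between 8 and 12 weeks, with Spearman's rho of 0.109, -0.0557 and -0.0594. Among 100 permutations of genotype within age, 62, 68 and 61 gave an r as large. Cyb5rl was the 1 gene whose genotype difference depended on age (limma F test, adjusted p = 0.0122), with 287 genes at an unadjusted p below 0.05. The Fmr1 difference at 12 minus that at 4 weeks was -4.20 ± 1.58 (SE) and did not pass (adjusted p = 1.00). Zfp287 (adjusted p = 0.821), Gpr146, Bace2, Nop14, a ribosome assembly gene, and Ddn followed in p (adjusted p = 1.00 each). The Cyb5rl call ended without CGG90 8 weeks replicate 1 or any wild-type 8-week library (adjusted p between 0.0514 and 0.0859), and with date as a fixed block (0.345, though not as a random block), a replicate block (0.663) or the libraries of low Fmr1 left out (0.129). Without the library labelled CGG90 12 weeks replicate 3, 2 genes were called.

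From 4 to 8 weeks, averaged over both genotypes, 5 genes changed. Camera at the preset correlation called 4 gene lists, of which 0 passed with an estimated correlation (smallest adjusted p = 0.622), and 47 of 100 splits of the libraries called as many. Kazald1, an insulin-like growth factor binding protein-like gene, rose by log2 1.86 ± 0.24 (SE), from a mean of 8.72 in both genotypes to 10.62 ± 0.34 (SD, n = 3) in wild type and 10.53 ± 0.35 in CGG90, or 3.62-fold (adjusted p = 0.00853), with all 6 libraries at 8 weeks above all 6 at 4 weeks. Btnl9, a butyrophilin-like gene, rose by 1.48 ± 0.23 (adjusted p = 0.0257) in 6 of 6 libraries, from values near the floor. Cyb5rl rose by 1.55 ± 0.19 (adjusted p = 0.00853) through the CGG90 libraries alone. H1f2, a linker histone gene, fell by 1.68 (SE 0.25) and Fkbp15, a gene of endosome transport, fell by 1.83 (SE 0.28), each in 6 of 6 libraries (adjusted p = 0.0256 for both). Pcp2 was at 0.18, Tardbp at -0.62 (adjusted p = 0.252), Fmr1 at 0.13 but at -0.44 with array weights, and Rpl10a at -0.06 but at 0.03 after centring of the arrays.

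Genes of the proteasome, the complex that degrades ubiquitin-tagged proteins, fell together from 4 to 8 weeks: 29 of 31 subunits were lower, with a median of -0.35 against -0.10 for all genes (camera adjusted p = 1.2e-05, adjusted p = 0.763 with an estimated correlation). Psmd6 was at -0.68, Psmd13 at -0.83, Psma5 at -0.67 and Psmc4 at -0.61. Cholesterol biosynthesis fell, with 16 of 18 genes lower and a median of -0.82 (adjusted p = 3.3e-04, and 0.622 with an estimated correlation), and adjusted over the list alone 7 genes passed. Its members Nsdhl, Mvd, Dhcr7 and Fdft1, all enzymes of the sterol pathway, were at -1.62, -1.18, -1.0 and -0.89. Heat shock proteins and chaperones fell, with 21 of 23 lower and a median of -0.37 (adjusted p = 3.2e-03, and 0.622 with an estimated correlation), among them Hsp90aa1 at -0.67, Dnaja1 at -0.53, Cct2 at -0.42 and Hspd1 at -0.37. Oligodendrocyte markers fell, with 15 of 15 lower and a median of -1.28 (adjusted p = 8.9e-05, and 0.878 with an estimated correlation), and 2 passed adjusted over the list alone. Fa2h, a gene of myelin lipid synthesis, was at -2.57, Mag at -1.46, Cldn11 at -1.35 and Cnp at -0.99. The mean of all other-cell markers was 8.27 in wild type and 8.28 in CGG90 at 4 weeks, against 7.67 and 7.65 at 8 weeks, with SDs between 1.02 and 1.26. With it as a covariate, the cholesterol list lay just outside the threshold (camera adjusted p = 0.0512), which does not show that its fall came from other cells.

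By unadjusted p, 1303 genes were below 0.05 from 4 to 8 weeks. Camera at the preset correlation called lists in simulated data that held no change, and with fry the heat shock list (adjusted p = 0.0202) remained past the threshold while proteasome (0.0693), cholesterol (0.0693) and oligodendrocyte genes (0.241) did not. The p53 list passed fry (adjusted p = 0.0392) but not camera (0.166), with 6 of 13 genes lower and a median of 0.04. The number of called genes was 55 without CGG90 8 weeks replicate 3 and 25 without wild-type 8 weeks replicate 2, and between 2 and 4 without each of the other 10 libraries of these ages. Calls of Kazald1 and Cyb5rl held in each of these, whereas Btnl9 (adjusted p between 0.0719 and 0.121) was lost without any 4-week library, CGG90 8 weeks replicates 1 or 2 or wild-type 8 weeks replicates 1 or 3. Fkbp15 (0.0543 to 0.121) was lost without wild-type 4 weeks replicates 1, 2 or 3, CGG90 4 weeks replicates 1 or 3, CGG90 8 weeks replicate 2 or wild-type 8 weeks replicates 1 or 3. H1f2 (0.0575 to 0.121) was lost without CGG90 4 weeks replicates 1, 2 or 3, wild-type 4 weeks replicate 3, CGG90 8 weeks replicates 1 or 2 or wild-type 8 weeks replicates 1 or 3. Btnl9 and Fkbp15 were also lost without the library labelled CGG90 12 weeks replicate 1. Fitted without the 12-week libraries, Kazald1, Cyb5rl and Fkbp15 were at an adjusted p of 0.0638, H1f2 at 0.0841 and Btnl9 at 0.144. The list count was 8 without wild-type 8 weeks replicate 2. No immunoprecipitation date held libraries of both ages, and 1 of the title numbers changes with age, so age and batch cannot be told apart. By the other title number the wild-type libraries at 8 weeks fall in the same run as those at 4 weeks, and there Kazald1 was at 10.23 to 10.85 against 8.11 to 9.23.

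From 8 to 12 weeks Cyb5rl fell by 1.51 (SE 0.19, adjusted p = 0.0134), in the libraries labelled CGG90. Immediate early genes, which neurons induce within minutes of activity, were higher in 6 of 6 tested cases, with a median of 0.77: Dusp1 at 1.11, Nr4a3 at 0.98, Jun at 0.86 and Egr1 at 0.69. Neuronal immaturity genes were higher in 15 of 21, with a median of 0.43, among them Dpysl3 at 1.52, Sox4 at 0.94, Ncam1 at 0.87 and Igf1 at 0.43. Genes of the p53 response were lower in 12 of 13, with a median of -0.34, among them Cdkn1a, a cell cycle inhibitor, at -1.06, Bcl2 at -0.41, Gadd45g at -0.40 and Aen at -0.34. Oxidative phosphorylation was lower in 54 of 65 with a small median of -0.09, against -0.04 for all genes, as in Atp5g2 at -0.50, Ndufa9 at -0.49, Atp5c1 at -0.31 and Ndufa10 at -0.29. All 4 lists passed camera at an adjusted p of 0.0270, and with an estimated correlation the adjusted p was 0.269 for the p53 list and 0.862 for the others. The p53 list passed fry (adjusted p = 5.2e-04), and the other 3 did not (0.933 each). Genes of small p that did not pass were Btnl9 at -1.35 (adjusted p = 0.168), Thsd7b at -0.97 (0.205), and Bod1l at 1.31, Entpd3, an ectonucleotidase gene, at 1.86 and Slc35a5, a nucleotide sugar transporter gene, at 0.98 (adjusted p = 0.261 each). Fmr1 was at -1.28 but at 0.54 with the libraries of low Fmr1 left out, and Tardbp at -0.13 but at 0.48 with the median of its probe sets. In that setting Dpysl3 was at -0.58 and Ncam1 at -0.74.

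Other-cell marker means were 7.95 in wild type and 8.17 in the libraries labelled CGG90 at 12 weeks, above the 8-week means of 7.67 and 7.65, and with their mean as covariate 0 lists passed (adjusted p of immediate early and immaturity genes 0.220, p53 response 0.118, oxidative phosphorylation 0.504). The loss of these calls alone does not show that the changes came from other cells. At 8 weeks, however, wild-type replicate 3 and CGG90 replicate 2 had the lowest marker means (6.30 and 6.36). They also had the lowest means of immediate early genes (4.73 and 5.15) and immaturity genes (7.31 and 7.45). Wild-type replicate 2, with the highest marker mean of that age (8.79), had the highest of both lists (7.59 and 8.76). These relations were not tested. On the 1 date that held libraries labelled CGG90 of both ages, those of 12 weeks being replicates 1 and 2 with their wild-type level of Fmr1, the medians were 0.31 for immediate early genes, 0.24 for immaturity genes, -0.15 for the p53 response and -0.09 for oxidative phosphorylation. Unadjusted p was below 0.05 for 670 genes. The number of called genes was 20 without CGG90 8 weeks replicate 3, 10 without wild-type 8 weeks replicate 2 and 2 without wild-type 12 weeks replicate 2. Cyb5rl was lost without wild-type 12 weeks replicates 1 or 3, any library labelled CGG90 12 weeks, or wild-type 8 weeks replicates 1 or 3 (adjusted p between 0.0531 and 0.0687), and with date as a fixed block (0.110). The list count was 0 without wild-type 12 weeks replicate 1, CGG90 8 weeks replicate 2 or wild-type 8 weeks replicate 3, 1 and 2 without the libraries labelled CGG90 12 weeks replicates 3 and 1, 7 without CGG90 8 weeks replicates 1 or 3, and 10 without wild-type 8 weeks replicate 2. In these and without wild-type 12 weeks replicate 3, the adjusted p of the lists that were lost was between 0.0617 and 0.566 for immediate early genes, 0.0596 and 0.566 for oxidative phosphorylation and 0.0664 and 0.522 for immaturity genes. The p53 list was lost in 6 cases (0.0504 to 0.141), wild-type 12 weeks replicate 2 and CGG90 8 weeks replicate 1 among them.

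From 4 to 12 weeks, the widest span, Kazald1 rose by log2 1.79 ± 0.24 (SE), from 8.72 in both genotypes to 10.47 ± 0.29 (SD, n = 3) in wild type and 10.55 ± 0.17 in the libraries labelled CGG90 (adjusted p = 0.0258). Golm2, a Golgi membrane gene, rose by 1.36 ± 0.20, or 2.57-fold (adjusted p = 0.0353). For both genes all 6 libraries at 12 weeks lay above all 6 at 4 weeks. Proteasome subunits fell, with 30 of 31 lower and a median of -0.44 against -0.12 for all genes (camera adjusted p = 1.5e-09, adjusted p = 0.946 with an estimated correlation, fry adjusted p = 0.0217), and adjusted over the list alone 14 subunits passed. Psmd13 was at -1.0, Psmd6 at -0.94, Psma5 at -0.88 and Psmb5, a catalytic subunit, at -0.80. Cholesterol biosynthesis fell, with 15 of 18 lower and a median of -0.69 (adjusted p = 2.7e-03, and 0.946 with an estimated correlation, fry 0.0741), and 5 genes passed adjusted over the list alone. Its mean per library followed the mean of the other-cell markers within groups (Pearson's r = 0.718 over 18 libraries after removal of group means, permutation p = 0.00947, Spearman's rho = 0.637, r = 0.726 without the 2 farthest libraries), and oligodendrocyte markers were lower by a mean of 0.79 without passing (exact permutation p = 0.165). With the marker mean as covariate the cholesterol median was -0.62 (adjusted p = 0.00897). Its members Fdps, Mvd, Hmgcs1 and Fdft1 were at -2.81, -1.63, -1.01 and -0.98. Just outside the threshold were Bod1l at 1.8, Ccdc28b at -0.96, Mcts2, a gene of translation re-initiation, at -1.29 and Sbds, a gene of ribosome maturation, at -1.32 (adjusted p = 0.0526 each). Tardbp was at -0.75 (adjusted p = 0.162), Fmr1 at -1.15 but at 0.67 with the libraries of low Fmr1 left out, Pcp2 at 0.08 and Rpl10a at -0.18.

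**Figure D3:**
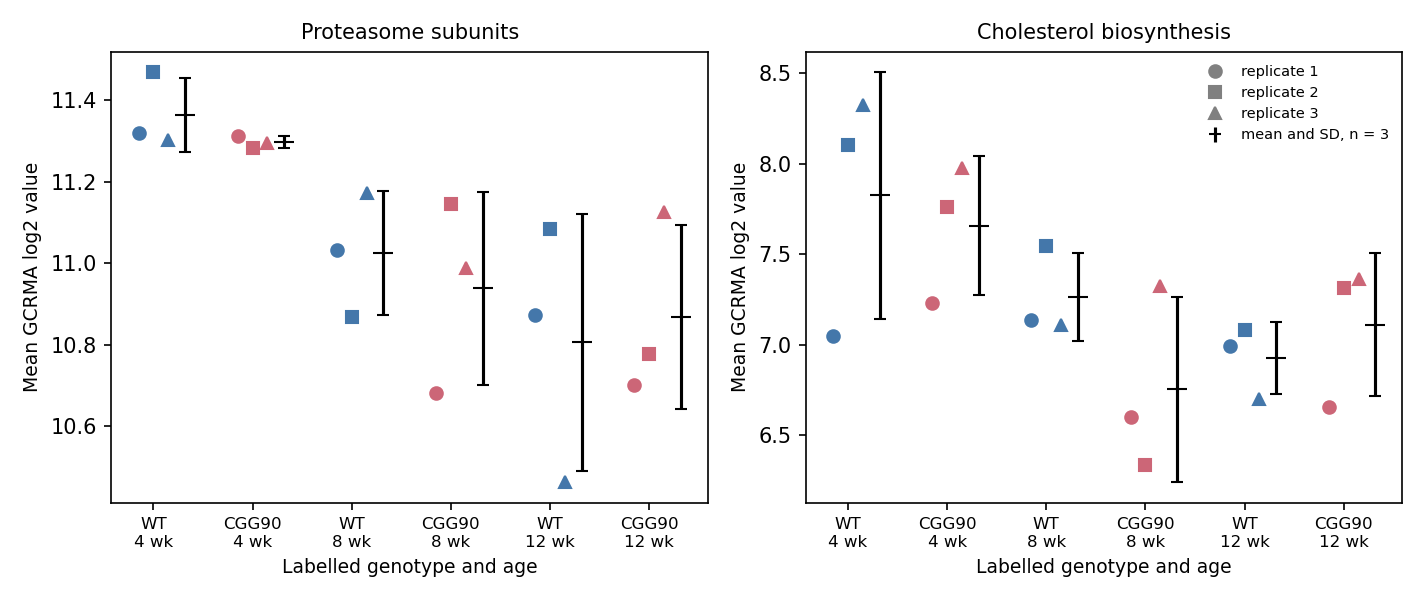
Mean log2 value (GCRMA) of 31 proteasome subunits (left) and 18 genes of cholesterol biosynthesis (right) in each library, by labelled genotype and age, with group means and SD (n = 3). The 4-week libraries lie between 11.28 and 11.47 for proteasome subunits, above all 12-week libraries, which lie between 10.46 and 11.13.

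Unadjusted p was below 0.05 for 1479 genes from 4 to 12 weeks. The number of called genes was 29 without wild-type 12 weeks replicate 2, 22 without the library labelled CGG90 12 weeks replicate 3, 1 without CGG90 4 weeks replicate 2 or wild-type 4 weeks replicate 1, and 0 without each of the other 8 libraries of these ages, where the adjusted p of Kazald1 and Golm2 was between 0.0524 and 0.0937. Without CGG90 4 weeks replicate 2 and wild-type 4 weeks replicate 1 Golm2 was lost (adjusted p = 0.0921 and 0.10). The 8-week libraries enter the error: 0 genes were called without CGG90 8 weeks replicate 3 or wild-type 8 weeks replicates 1 or 3, Kazald1 alone without replicate 2 of either genotype, and 4 genes without CGG90 8 weeks replicate 1. Both calls ended with the libraries of low Fmr1 left out (0.467 each), with a fit of the compared libraries alone (0.173 each) and with a replicate block (0.0602 and 0.0797), and Golm2 ended with the median of its probe sets (0.141) and with date as a random block (0.0627). Camera called 5 lists without CGG90 4 weeks replicate 1, and 3 without the libraries labelled CGG90 12 weeks replicates 1 or 2, wild-type 12 weeks replicate 3 or any wild-type 4-week library. As from 4 to 8 weeks, no immunoprecipitation date held libraries of both ages.

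Within wild type, from 4 to 12 weeks, proteasome subunits fell, with 31 of 31 lower (median -0.50, adjusted p = 5.6e-09, and 0.683 with an estimated correlation), with Psmd13 at -1.08, Psmd6 at -0.99, Psma5 at -0.98 and Psmd14 at -0.70. Cholesterol biosynthesis fell, with 15 of 18 lower (median -1.06, adjusted p = 1.5e-03, and 0.705 with an estimated correlation), with Fdps at -3.29, Mvd at -1.57, Hmgcs1 at -1.23 and Fdft1 at -1.15, and 4 genes passed adjusted over the list alone. CGG repeat RNA-binding proteins fell, with 20 of 23 lower (median -0.56, adjusted p = 4.9e-03, and 0.705 with an estimated correlation), with Ddx6, an RNA helicase, at -1.13, Tardbp at -1.03, Hnrnpc at -0.83 and Hnrnpa2b1 at -0.65. Heat shock proteins fell, with 21 of 23 lower (median -0.41, adjusted p = 4.9e-03, and 0.683 with an estimated correlation), with Fkbp4 at -0.98, Dnaja1 at -0.82, Stip1 at -0.71 and Hspd1 at -0.67. Oligodendrocyte markers fell, with 14 of 15 lower (median -1.12, adjusted p = 0.0251, and 0.994 with an estimated correlation), with Cldn11 at -1.36, Olig1 at -1.17, Ugt8a at -1.13 and Cnp at -0.92, while the mean of all other-cell markers was 8.27 at 4 and 7.95 at 12 weeks. By fry, the proteasome (adjusted p = 0.0360) and heat shock lists (0.0230) passed, as did the p53 list (0.0230), which camera did not call (0.783), and cholesterol (0.145), CGG repeat RNA-binding (0.145) and oligodendrocyte genes (0.639) did not. In limma 0 genes passed, with 890 below an unadjusted p of 0.05. Closest were Golm2 at 1.70, Larp7, a gene of transcription elongation control, at -1.93, Parp2, a DNA repair enzyme, at -2.40 and Sbds at -2.01 (adjusted p = 0.0697 each), then Ddn at 3.66 and Nectin4 at 2.29 (0.158 each).

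Leaving out wild-type 4 weeks replicate 3, the library with an other-cell marker mean of 9.27, ended the calls of CGG repeat RNA-binding proteins (median -0.21, adjusted p = 0.243), cholesterol (-0.59, 0.0766) and oligodendrocyte genes (-0.67, 0.601). Without wild-type 12 weeks replicate 2 the RNA-binding (0.156), heat shock (0.0618) and oligodendrocyte lists (0.156) were lost and 4 genes were called. Oligodendrocyte genes were also lost without wild-type 12 weeks replicate 1 (0.181) or wild-type 4 weeks replicate 2 (0.0776), and 1 gene was called without wild-type 4 weeks replicate 3.

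Within the libraries labelled CGG90, from 4 to 12 weeks, proteasome subunits fell, with 28 of 31 lower (median -0.43, camera adjusted p = 2.7e-05, adjusted p = 0.899 with an estimated correlation, fry adjusted p = 0.583), with Psmd6 at -0.88, Psmb1 at -0.84, Psma5 at -0.79 and Psma6 at -0.50. In limma 0 genes passed, with 823 below an unadjusted p of 0.05. Closest were Gpr146 at 2.3 (adjusted p = 0.109), Bod1l at 2.3 and Bace2 at -2.49 (0.204 each), Kazald1 at 1.83 (0.222), and Slc35e4 at -2.01 and Tefm, a mitochondrial transcription factor gene, at -1.40 (0.507 each). Fmr1 was at -3.25 through the libraries labelled CGG90 12 weeks replicates 1 and 2, and at 0.38 with them left out, where 0 genes and 4 lists passed with 1 library at 12 weeks that is assumed to vary like those of the other groups. Without the library labelled CGG90 12 weeks replicate 3, 7 genes were called, without wild-type 8 weeks replicate 2 Bace2 and Gpr146 were called, and the list count was 3 without the library labelled CGG90 12 weeks replicate 2 or CGG90 4 weeks replicate 1, and 2 without CGG90 4 weeks replicates 2 or 3. The change with age was tested for a difference between genotypes, and 0 lists passed (smallest adjusted p = 0.107), so the lists called in wild type alone are not shown to differ from CGG90.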

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

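The tests of the low Fmr1 values in the libraries labelled CGG90 12 weeks replicates 1 and 2 were chosen only after the values were seen, while the rules that picked the other results here were fixed before.

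In the libraries labelled CGG90 12 weeks replicates 1 and 2, Fmr1 stood at log2 7.10 and 6.03, the level of wild type, against 12.01 in the library labelled CGG90 replicate 3, and with a second probe set at 6.82 and 5.06 against 9.88, where the highest wild-type library had 6.42. A swap with a wild-type library of the same age needs a wild-type library at the transgenic level, and the highest of the 3 had 8.39 where the lowest CGG90 library at 4 and 8 weeks had 11.01, which argues against it. Loss of Purkinje cell RNA was tested on 18 markers, which differed from the library labelled CGG90 replicate 3 by a median of -0.24 (quartiles -0.49 and -0.08), far less than the -5.45 of Fmr1, and a CGG90 8-week library of the same immunoprecipitation date had Fmr1 at 11.01. Mice without the transgene, or RNA of other wild-type mice, remain open. Each library pooled 4 mice by its label, so mice without the transgene would have to fill both pools or nearly so. Chance would give 50.3 genes that separate the genotypes at both 4 and 8 weeks if 10% did so at each age. The shares seen were 4.35% and 7.22%, and the genes that did so at both ages numbered 24. Without Fmr1 and Zfp28, 22 of them put these libraries at -0.12 on a scale where wild type at 12 weeks is 0. The library labelled CGG90 replicate 3 lay at -0.31, so these genes do not tell the genotypes apart at 12 weeks. A biological loss of the transcript in CGG90 mice at 12 weeks could not be tested apart from an absent transgene. Zfp28, at 5.13 and 7.01 in these libraries against 2.79 to 2.88 in wild type, is the 1 named gene that kept to their label at all ages, with 1 of its 4 probe sets, the others being near the floor. It stands out by this very separation, so it does not decide whether the label is right. Chance would give 2.52 such genes at a share of 10% per age, which the shares seen did not reach.

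Cyb5rl was picked out because its genotype difference changed with age (limma F test, adjusted p = 0.0122). As in the 8-week comparison, its error was pooled with groups near the floor. The following results were picked out because every library moved in one direction in one group and in the opposite direction in another, among 85 named genes. Their limma F tests gave adjusted p between 0.821 and 1.00, so none of these differences between groups passed. At 8 and 12 weeks genotype also coincides with 1 of the title numbers. Ddn differed between the labelled genotypes, CGG90 minus wild type, by 0.91 at 8 weeks and -3.71 at 12 weeks. Gpr146 was at -0.52 and 1.91 at these ages, Nop14 at -1.31 and 1.43, and Snhg5 at -0.71 and 1.45. Parp2 differed by -0.88 at 4 weeks and 1.33 at 12 weeks. Between 4 and 8 weeks the difference went from 0.49 to -0.68 for Tefm and from 0.67 to -1.55 for Zfp287. From 4 to 12 weeks Hinfp was at -0.87 in wild type and 0.73 in the libraries labelled CGG90, and Miga2 at 0.53 and -1.02. Among all 10068 genes, 79 separated the genotypes completely in opposite directions at a pair of ages. Chance would give 143 if 10% of genes separated the genotypes at each age. The shares seen were 4.35%, 7.22% and 8.62% at 4, 8 and 12 weeks, so 143 is too high a reference. Whether the pattern is unusual is therefore not decided.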

How the results depend on the processing

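Results below with the libraries of low Fmr1 (labelled CGG90 12 weeks replicates 1 and 2) left out, with the marker covariate, with other Fmr1 probe sets, for the correlation of genotype differences, for single lists, and for the 4-week libraries alone with a replicate block or with list tests come from alternatives chosen after the data were seen, and the others were planned. With the libraries of low Fmr1 left out, the CGG90 group at 12 weeks holds 1 library, which is assumed to vary like those of the other groups. Over 34 alternative fits, 294 values of counts and checks stayed within 1.5 times of those reported or within their spread and 161 moved, and of the values of named genes and lists 3891 kept direction and side of the threshold, 156 kept direction but no longer passed, 83 passed newly and 40 changed sign. Except where a cause is given, the cause was not tested. The proteasome list from 4 to 12 weeks kept its direction and passed in every alternative run for it but camera with an estimated correlation, with medians between -0.52 and -0.30. List tests were not run with array weights, cyclic loess, eBayes trend and robust estimation, or only the arrays compared. They were also not run with all probe sets or the median of a gene's probe sets. Signal close to the array floor (a group mean below log2 3) limits 11 of 85 named genes, Bace2, Btnl9, Cyb5rl, Entpd3, Gpr146, Nectin4, Nsdhl, Sox4, Thsd7b, Zfp28 and Zfp287, whose differences from such a group are lower bounds, and signal close to the maximum limits Pcp2. IP date as a fixed block gave no value for comparisons with 4 weeks, whose dates hold no other age.

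Counts of genes that moved are given by setting. With array weights they were 1 in the genotype comparison at 4 weeks, 1 averaged over ages, 311 from 4 to 8 weeks (162 higher, 149 lower), 3 from 8 to 12 weeks, 24 from 4 to 12 weeks, 4 in wild type and 3 in CGG90. With only the arrays compared, which leaves fewer degrees of freedom and drops the spread of the other groups, they were 1 at 4 weeks, 0 at 8 weeks, 1 from 4 to 8 weeks, 0 from 8 to 12 weeks and 0 from 4 to 12 weeks. With the libraries of low Fmr1 left out they were 1 at 4 weeks, 1 averaged over ages, 0 for dependence on age, 2 from 4 to 8 weeks, 0 from 8 to 12 weeks and 0 from 4 to 12 weeks. The stricter filter (log2 of at least 6), which no longer tests Cyb5rl, gave 0 at 8 weeks, 0 for dependence on age, 2 from 4 to 8 weeks, 0 from 8 to 12 weeks and 7 from 4 to 12 weeks. Without a filter there were 57 from 4 to 8 weeks, 26 from 4 to 12 weeks, 7 in wild type and 1 in CGG90. All probe sets past the filter gave 28 from 4 to 8 weeks and 4 from 4 to 12 weeks, and the median of a gene's probe sets gave 2 and 7. Quantile normalization gave 2 at 8 weeks, 3 from 4 to 8 weeks and 7 from 4 to 12 weeks, centring of each array gave 4 from 4 to 12 weeks, and cyclic loess gave 0 for dependence on age, 3 from 4 to 8 weeks, 0 from 8 to 12 weeks, 8 from 4 to 12 weeks and 1 in CGG90. With eBayes trend and robust estimation there were 0 for dependence on age, 33 from 4 to 8 weeks, 0 from 8 to 12 weeks, 34 from 4 to 12 weeks and 3 in wild type. A replicate block gave 0 at 8 weeks, 0 for dependence on age, 2 from 4 to 8 weeks, 0 from 8 to 12 weeks and 1 from 4 to 12 weeks. IP date as a fixed block gave 0 at 8 weeks, 0 for dependence on age and 0 from 8 to 12 weeks, since few libraries share a date, and as a random block (consensus correlation 0.0973) it gave 1 from 4 to 12 weeks. The marker covariate gave 1 averaged over ages, 17 from 4 to 8 weeks and 33 from 4 to 12 weeks. A threshold of 0.1 gave 22 from 4 to 8 weeks, 16 from 4 to 12 weeks and 4 in wild type. With the dimmest Fmr1 probe set, 1 of 9 libraries labelled CGG90 lay above wild type in place of 7, and with the second probe set 8.

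Counts of lists moved as follows. Camera with an estimated correlation gave 0 in each of the 5 comparisons of ages, and fry gave 2 from 4 to 8 weeks, 1 from 8 to 12 weeks, 1 from 4 to 12 weeks, 3 in wild type and 0 in CGG90. Without a filter there were 2, 3 and 2 in the genotype comparisons at 4, 8 and 12 weeks, 7 from 4 to 8 weeks, 7 from 4 to 12 weeks and 4 in CGG90, and with the stricter filter 2 in CGG90. The 4-week libraries alone gave 1 at 4 weeks. With the libraries of low Fmr1 left out there were 2 in the genotype comparison at 12 weeks, 4 from 4 to 12 weeks and 4 in CGG90, and r between the genotype differences at 8 and 12 weeks was -0.163. The marker covariate gave 0 from 8 to 12 weeks and 4 from 4 to 12 weeks.

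Leaving out each library in turn gave ranges of gene counts of 0 to 1 at 4 weeks (Fmr1 without the library labelled CGG90 12 weeks replicate 3, Bace2 without wild-type 8 weeks replicate 2), 1 to 2 at 8 weeks, 0 to 2 at 12 weeks, 0 to 2 averaged over ages, 0 to 2 for dependence on age, 2 to 55 from 4 to 8 weeks, 0 to 20 from 8 to 12 weeks, 0 to 29 from 4 to 12 weeks, 0 to 4 in wild type and 0 to 7 in CGG90. Ranges of list counts were 0 to 5 at 4 weeks, 0 to 3 at 8 weeks, 0 to 1 at 12 weeks, 0 to 2 averaged over ages, 4 to 8 from 4 to 8 weeks, 0 to 10 from 8 to 12 weeks, 2 to 5 from 4 to 12 weeks, 2 to 6 in wild type and 1 to 3 in CGG90.

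Signs changed for Fmr1, Tardbp, Pcp2, Rpl10a, Cyb5rl, Dpysl3 and Ncam1. With array weights Tardbp at 4 weeks was at 0.048, Pcp2 in its dependence on age at 0.020 and Fmr1 from 4 to 8 weeks at -0.44. The median of a gene's probe sets gave 0.091 for the dependence of Pcp2 on age, -0.16 for Fmr1 from 4 to 8 weeks, and from 8 to 12 weeks -0.58 for Dpysl3, -0.74 for Ncam1 and 0.48 for Tardbp. IP date as a fixed block gave -0.40 for Rpl10a at 8 weeks, -1.07 for Fmr1 and 0.27 for Rpl10a at 12 weeks, and 0.044 for the dependence of Pcp2 on age. Quantile normalization gave -0.0055 for Rpl10a at 8 weeks, centring 0.033 for Rpl10a from 4 to 8 weeks, and cyclic loess -0.022 for the dependence of Cyb5rl on age (12 against 4 weeks, where neither group holds its signal). With the libraries of low Fmr1 left out Fmr1 was at 0.54 from 8 to 12 weeks, 0.67 from 4 to 12 weeks and 0.38 in CGG90. Leaving out each library gave ranges of -0.0082 to 0.13 for Pcp2, -0.23 to 0.029 for Rpl10a and -0.36 to 0.031 for Tardbp at 4 weeks, -0.090 to 0.15 for Rpl10a at 8 weeks, and -1.37 to 1.62 for Fmr1 and -0.26 to 0.016 for Rpl10a at 12 weeks. Ranges for the dependence on age were -0.088 to 0.047 for Pcp2 and -0.13 to 0.15 for Rpl10a. From 4 to 8 weeks Fmr1 ranged from -0.17 to 0.56 and Rpl10a from -0.13 to 0.022, and from 8 to 12 weeks Tardbp from -0.26 to 0.023.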

Other observations

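Gene groups outside the lists named above stayed below the threshold. Over the 9 comparisons tested with lists, 21 of the 30 lists passed in none with camera at the preset correlation. The smallest adjusted p was 0.0704 for astrocyte and Bergmann glia markers and for cytoplasmic ribosomal proteins, both from 8 to 12 weeks. Granule cell markers reached 0.172, cerebellar interneuron markers 0.163, microglia markers 0.242, endothelial and mural cell markers 0.373, blood cell markers 0.163, oligodendrocyte precursor markers 0.551, and choroid plexus and Purkinje markers 0.512 each. Genes of calcium handling and ion channels reached 0.223, of group I metabotropic glutamate receptor signalling 0.670, and hereditary ataxia genes 0.645. The smallest values of FMRP and its partners (0.405), the unfolded protein response (0.471), microRNA biogenesis (0.231), perineuronal net and matrix genes (0.230), interferon response and clock genes (0.512 each) and antigen presentation (0.435) were no closer.

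The sex-linked list had a smallest adjusted p of 0.422, and its genes varied between libraries that by their labels each pooled 2 males and 2 females. With its brightest probe set Kdm5d, on the Y chromosome, had a log2 value of 2.18 in CGG90 4 weeks replicate 3 and 2.64 in CGG90 8 weeks replicate 1, with 2.87 in wild-type 12 weeks replicate 3 and values of up to 7.61 elsewhere. Its other probe sets were at 2.65 or below in all libraries. Eif2s3y, also Y-linked, was at 2.61 and 2.43 with its probe sets in CGG90 4 weeks replicate 3, but at 4.07 and 3.21 in CGG90 8 weeks replicate 1 and 4.63 and 4.27 in wild-type 12 weeks replicate 3. The values of CGG90 4 weeks replicate 3 conflict with the 2 males of its label if these genes report the sex of a pool, and this library enters all results at 4 weeks. Xist, the female gene of the list, was at 3.67 or below in every library with any of its probe sets, although each label gives 2 females. A low value of a sex-linked gene thus does not by itself contradict a label here.

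The tests of markers of other cells and of the proteasome list that follow were chosen only after these results were seen. The rule for reading the counts over other splits of the libraries was also written only afterwards.

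Markers of other cerebellar cells differed between replicates by up to log2 2.49 within a group. Across the 18 libraries, after removal of group means, 10 pairs of 5 marker lists (granule cells, astrocytes, oligodendrocytes, microglia and endothelial cells) correlated with Pearson's r between 0.867 and 0.980 and Spearman's rho between 0.798 and 0.971 (permutation p of r at most 0.00248 after adjustment over 15 relations, r at least 0.795 without the 2 farthest libraries), and each list correlated with the Purkinje markers at r between -0.774 and -0.699. A varying share of RNA from other cells in the whole library is a candidate explanation. The abundant markers Mbp (10.60 to 14.05), Cbln1 (9.82 to 12.64) and Laptm5 (5.51 to 10.60) varied widely, but Hopx (11.94 to 12.59) did so less. Slc32a1 (10.85 to 12.15) also varied less, but it belongs to the interneuron list, outside these 5, and is not counted against this explanation. Whether its signal came from interneurons or from Purkinje cells was not tested. Ribosome capture by the tag is meant to remove RNA of other cells, and how far it did so was not tested. The date of immunoprecipitation as the whole cause is argued against by the shared date at 8 weeks, where the libraries of both genotypes differed by log2 2.11, but at 4 weeks the pairing by date had the smallest differences (0.24, 0.26 and 0.05), which 1 of the 6 possible pairings gave, too few to decide. Genotype and age held 10.6% of the variance of the marker mean (permutation p = 0.917), but they do not vary within a group, so this share decides nothing about differences between replicates, and differences between the pooled mice stay open and untested.

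The proteasome list was lower at 12 than at 4 weeks by a median of -0.44. RNA from other cells as the whole cause is argued against by the fit with the marker mean as covariate, which left -0.44 with 30 of 31 subunits lower. All genes moved by a median of -0.12, and centring of each array left -0.30 with 28 of 31 lower. A uniform shift of the array could thus account for part of the fall, but not for all of it. Camera at the preset correlation gave adjusted p of 3.2e-09 and 8.6e-08 in these fits. It called too many lists in simulated data, and with an estimated correlation the main fit gave 0.946, so these p-values carry no weight here. An array batch cannot be told apart from age, since libraries of these ages share 0 title numbers. With the list mean per library as the unit, the exact permutation p was 0.005, the smallest that 400 arrangements can give, and 0.15 adjusted over the 30 lists, below which a single list could not get, so this test decides nothing and correlated genes in few libraries stay open. A change of the mice with age remains open and untested.

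Other splits of the same libraries were counted. For genes, few splits gave as many calls from 4 to 8 weeks (5 genes, 2 of 100 splits with the real one included, 82 at most in another). The same held from 4 to 12 weeks (2 genes, 3 of 100, 2 at most in another). These shares were not adjusted over the comparisons. The splits also parted libraries of a shared immunoprecipitation date, which the real split by these ages keeps together, so chance is not excluded. It was also not excluded for the dependence on age (1 gene, 33 of 100, 50 at most) or from 8 to 12 weeks (1 gene, 34 of 100, 3 at most). For lists it was not excluded from 4 to 8 weeks (4 lists, 47 of 100, 16 at most) or from 8 to 12 weeks (4 lists, 28 of 100, 13 at most). Nor was it from 4 to 12 weeks (2 lists, 68 of 100, 14 at most). Where the real count is 0 every split reaches it, so the share decides nothing. This was so averaged over ages, for genes (100 of 100, 6 at most) and for lists (100 of 100, 15 at most). With 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real and the highest other counts of genes were 0 and 2 at 4 weeks, 1 and 51 at 8 weeks, 0 and 20 at 12 weeks, and 0 and 1 from 4 to 12 weeks in wild type and in the libraries labelled CGG90, and those of lists were 0 and 14, 0 and 12, 0 and 2, 5 and 12, and 1 and 10. The real counts of genes were reached by 10, 3, 10, 10 and 10 of the 10 splits and those of lists by 10, 10, 10, 5 and 7. Of the 6 libraries at 4 weeks the replicate numbers are also dates, and the real split parts all 3 pairs.

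The libraries varied together within groups. The first component of the values after removal of group means held 27.3% of the variance and correlated with the mean of the other-cell markers at an absolute r of 0.969 (rho 0.936, permutation p = 1.4e-04, r 0.956 without the 2 farthest libraries). Among the splits with the most calls was that at 12 weeks with 20 genes. It set libraries with other-cell marker means between 8.20 and 8.24 against 7.62 to 8.04. Their Purkinje marker means were 11.76 to 11.96 against 12.17 to 12.29. With the higher other-cell means were the libraries labelled CGG90 12 weeks replicates 1 and 2, of low Fmr1, and wild-type replicate 3. The library labelled CGG90 12 weeks replicate 3 was on the other side. Which of these differences the 20 calls follow was not tested. The other-cell marker means overlapped in the split at 8 weeks that called 51 genes (6.30 to 8.17 against 7.91 to 8.79). They also overlapped in the split that called 82 genes across 4 and 8 weeks (6.30 to 8.23 against 8.17 to 9.32). The other-cell markers thus did not separate these libraries.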
